A study of Gallus gallus with 4 samples.

How the data were processed

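RNA was measured by sequencing of poly-A selected transcripts from granulosa cells of hens (Gallus gallus) aged 10 to 15 months. Granulosa cells form the layer that surrounds the oocyte of an ovarian follicle. Per the labels, cells lying close to the germinal disc (proximal) and away from it (distal) were taken from follicles at the F5 and the F1 stage of the preovulatory hierarchy, in which F1 is the follicle nearest to ovulation. There were 4 libraries, 1 for each combination of position and follicle. The labels do not say how many hens or follicles went into a library, and follicles of 6 mm, which the extraction protocol also mentions, were not analysed here.

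The deposited tables held gene expression as FPKM (fragments scaled to gene length and to the library total), which the authors had computed before deposit. Per the submitters' processing notes, TopHat2 2.0.12 and HTSeq 0.6.1 were used. The genome build is not given in the sources used here, so coordinates are printed as the authors' files give them without a build. The tables also held the authors' log2 fold changes of proximal against distal cells for each follicle, per the file headers. Of 19309 rows with a gene identifier, 17108 were Ensembl identifiers and 2201 were unannotated loci numbered by the authors. Another 2 rows without a gene were left out. Gene names were taken from the files. A name was used for 11797 rows, where it was unique, stood in a RefSeq gene table of assembly GRCg7b and was not contradicted by its chromosome.

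FPKM values are not counts, and the sequencing depth was recovered from them. Within each gene the FPKM ratios between libraries, after a constant for the library totals, fitted whole reads for 16894 of the 16894 genes above 0. The tolerance was 1e-08, and a gene above 0 in a single library fits by construction. The totals that scale FPKM came to 16654793 reads for F5 proximal, 17351242 for F5 distal, 18020270 for F1 proximal and 13948790 for F1 distal cells, and the recovered reads made up 97.3% to 97.9% of them. Recovery was tested on simulated libraries, where 96.6% of 16563 genes returned their exact reads. A gene's reads are the smallest whole numbers that fit, so reads of a gene whose true values share a common factor are understated and their intervals are then too wide. Recovered reads were used for depth, counting intervals, thinning, an added weighted fit and tests in the closing section.

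Analyses used log2(FPKM + 1), with a pseudocount of 1 FPKM, and kept 11203 genes with a mean of at least 1 FPKM over the 4 libraries. A difference on this scale understates the change of low genes. With 1 library per group no difference between a pair of libraries has a replicate check, and no p-value is given for one. Such differences were described by a size rule of 2-fold on the log2(FPKM + 1) scale. Folds of single genes are ratios of FPKM, with a 95% exact (Clopper-Pearson) binomial interval from the recovered reads. Where a library had 0 reads, the fold is a lower bound against a floor of 3 reads per library. Intervals and bounds cover counting error only, and not differences between hens or follicles.

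The only tests across libraries were additive fits with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend, Benjamini-Hochberg adjustment, two-sided, threshold 0.05), in which position and follicle were fitted together. They leave 1 residual degree of freedom, which holds the interaction of position and follicle. The labels do not show that the libraries come from separate animals, so these p-values measure the spread among these 4 libraries, which may be technical. On simulated libraries with 11111 genes, the fit of position recovered 3.03% of genes changed 2-fold and 71.0% of those changed 4-fold, with 5 false calls. The simulated genes had the same position fold in both follicles and no interaction, so these rates may not hold for the libraries analysed. A test with edgeR, planned for the case that whole reads could be recovered, was not run although they were. Count models were kept here to deposited counts. Limma with voom weights on the recovered reads took its place.

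Before the data were examined, 22 gene lists with 717 genes were fixed, of which 550 were found by name. For each list the median log2 difference was set against 10000 random lists of the same size, matched on mean expression in 10 bins, and its percentile is given as a description of these libraries. In simulations with 8000 genes, 4.00% of unchanged lists of 25 genes and 99.0% of lists shifted by 0.5 on the log2 scale fell outside the 2.5 to 97.5 percentiles. The simulated genes varied independently, and fewer random lists were drawn there than for the data. Genes of a real list may vary together, so these rates may not hold for the lists used. Genes were named by a rule fixed at the same time. Among genes with a usable symbol and a mean of at least 5 FPKM it took the 6 highest and 6 lowest in each pair of libraries, the 8 highest and 8 lowest by the smaller of a factor's 2 same-direction differences, and up to the 8 largest called by a fit in each direction. It added up to 4 list members with the largest difference in a comparison, the 4 with the highest mean, and STAR, CYP11A1, LHCGR, FSHR, AMH and FOXL2.

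The alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter on low values, a mean of at least 5 FPKM, rescaling to a common total, and median-ratio scaling, and for the fits also no trend and the other factor left out. Thinning of the recovered reads to the shallowest library and the voom fit were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.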

Results

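Gene expression was measured in granulosa cells proximal and distal to the germinal disc, the small patch of cytoplasm that holds the oocyte nucleus, in F5 and F1 follicles of the chicken ovary. Each of the 4 groups had 1 library, so values below are those of single libraries. The libraries held between 13948790 and 18020270 reads, and F1 distal cells had the fewest. ZP3, the egg coat protein that granulosa cells of birds make, took 1.98% of the reads in F5 proximal cells and 2.04% in F5 distal cells, but 11.4% in F1 proximal and 15.4% in F1 distal cells. Shares of the variance among the 4 libraries were taken around the median of all 11203 genes, which leaves out shifts common to all genes. Of this variance, 79.2% lay between F1 and F5, 15.1% between proximal and distal cells, and 5.66% in the interaction of position and follicle. Across all genes the median log2 difference was 0.07 for F5 proximal against F5 distal cells, 0.20 for F1 proximal against F1 distal cells, -0.27 for F1 against F5 in proximal cells and -0.40 in distal cells. Under median-ratio scaling these medians came to -0.04, -0.04, 0.00 and 0.00, and list values are therefore given with a percentile among random lists of like expression.

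The first comparison asked how cells near the germinal disc differ from those far from it in F5 follicles. AMH (ENSGALG00000024368, chromosome 28, 1956623 to 1960825), a hormone of the TGF-beta family made by granulosa cells of small follicles, stood at 21.2 FPKM in proximal and 1.55 FPKM in distal cells, 13.7-fold higher (95% interval 10.8 to 17.5). CCNO (ENSGALG00000028595, chromosome Z, 16589252 to 16590557), a cyclin, was 10.1-fold higher (8.30 to 12.4). ZP2 (ENSGALG00000002428, chromosome 14, 15059196 to 15066978), an egg coat glycoprotein, was 10.8-fold higher (8.92 to 13.1). NGFR, a neurotrophin receptor, was 11.7-fold higher (9.88 to 13.9), and NBL1, a secreted antagonist of bone morphogenetic proteins, was 8.78-fold higher (7.54 to 10.3). TMEM184A was 25.7-fold higher, on 9 distal reads (13.3 to 56.9). On the distal side the folds were smaller. FMOD (ENSGALG00000003546, chromosome 26, 5167693 to 5174255), a collagen-binding proteoglycan, was 3.14-fold lower in proximal cells (2.97 to 3.32), TPBG was 2.23-fold lower (1.81 to 2.77) and STC1, a secreted glycoprotein hormone, was 2.03-fold lower (1.85 to 2.23). By the size rule 244 genes were at least 2-fold higher and 36 at least 2-fold lower in F5 proximal cells. With a pseudocount of 5 these counts came to 68 and 1.

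Of the gene lists, 8 measured oocyte markers had a median log2 difference of 1.00 in F5, at percentile 99.99, and 4 of them were at least 2-fold higher in proximal cells. BMP15, an oocyte growth factor, had 208 reads in proximal and 5 in distal cells, 43.3-fold higher (18.3 to 135), and DAZL, a germ cell RNA-binding protein, had 128 and 3, 44.5-fold higher (14.9 to 218). Ribosomal protein genes lay lower in proximal cells, with a median of -0.36 over 62 genes at percentile 0.00, and none differed 2-fold. Cholesterol synthesis and uptake genes had a median of -0.29 over 19 genes and nuclear-encoded oxidative phosphorylation genes of -0.12 over 48, both at percentile 0.00. Cell cycle genes had a median of 0.17, at percentile 99.6, and 1 of 45 was at least 2-fold higher, namely CCNB2, a mitotic cyclin, at 104.5 against 35.4 FPKM. WNT signalling genes had a median of -0.07 over 23 genes at percentile 0.54, which moved to 0.05 at percentile 51.5 without the filter on low values. Endothelial markers had a median of 0.34 over 5 genes at percentile 98.3; EMCN stood at 10.6 against 0.986 FPKM and CLDN5 at 30.9 against 6.64 FPKM, while the levels of EGFL7 were 51.2 and 49.6 FPKM. The endothelial median came to percentile 96.5 with a pseudocount of 5 and to 63.9 without the filter. ID1, a target of bone morphogenetic protein signalling, was 5.54-fold higher in proximal cells (5.04 to 6.10), and SMAD6, an inhibitor of that pathway, 3.26-fold higher (2.86 to 3.73). The whole TGF-beta and BMP signalling list did not stand out in F5. Its median was 0.09 over 22 genes at percentile 86.7, with 12 above 0 and 10 below.

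The same question was asked in F1 follicles. WNT4 (ENSGALG00000004790, chromosome 21, 6300381 to 6312118), a signalling ligand of ovarian somatic cells, stood at 236.9 FPKM in proximal and 8.72 FPKM in distal cells, 27.2-fold higher (23.4 to 31.7), whereas in F5 it stood at 1600.3 and 1624 FPKM. INHBB (ENSGALG00000028770, chromosome 7, 25068118 to 25068894), the beta B subunit of activin and inhibin, was 51.5-fold higher in F1 proximal cells on 6 distal reads (23.4 to 141.1), with 378.3 and 449.1 FPKM in F5. MRC2, an endocytic collagen receptor, was 84.4-fold higher (52.6 to 145), CLDN1, a tight junction protein, 62.6-fold (28.5 to 171), CCNO 44.0-fold (28.0 to 73.3) and TMEM72 36.6-fold (25.6 to 54.0). FST, which binds activin, was 11.2-fold higher (7.59 to 17.2). Among genes with a usable symbol and a mean of at least 5 FPKM, the lowest in F1 proximal cells were STC2, 3.38-fold lower (2.47 to 4.67), PDE1B, 2.42-fold lower (2.08 to 2.81), ADCYAP1R1, 2.34-fold lower (1.99 to 2.76), and FMOD, 2.18-fold lower (2.07 to 2.30). In all, 580 genes were at least 2-fold higher and 34 at least 2-fold lower. The share of higher genes was 94.5%, and under median-ratio scaling, with 460 higher and 91 lower, it was 83.5%.

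Cell cycle genes lay higher in proximal cells of F1. Their median log2 difference was 1.46 at percentile 100, 31 of 45 members were at least 2-fold higher in proximal cells, 14 were within 2-fold, and all 45 lay above 0. CDK1, the mitotic kinase, was 15.2-fold higher (9.83 to 24.9), RRM2, which makes deoxynucleotides, 63.2-fold on 6 distal reads (28.8 to 173), and TOP2A 2.56-fold (2.26 to 2.90). Whether this differs from the shift in F5 was not tested, since the only residual degree of freedom holds that difference. The 8 oocyte markers had a median of 1.51 at percentile 100, and 5 were at least 2-fold higher. BUB1B, at 7.57 against 1.89 FPKM, is among these 5 and is also counted in the cell cycle list. DAZL had 102 proximal and 0 distal reads, at least 26.3-fold higher. TGF-beta and BMP signalling genes had a median of 0.39 over 22 genes at percentile 99.9, and immediate early and stress genes of 0.43 over 14 genes at percentile 99.4. The first moved to percentile 90.5 without the filter and the second to 96.7 at a mean of at least 5 FPKM. Cholesterol synthesis and uptake genes again lay lower in proximal cells, with a median of -0.35 at percentile 0.00 and 19 of 19 below 0. Ribosomal protein genes had a median of -0.13 at percentile 0.00 and oxidative phosphorylation genes of -0.01 at percentile 1.23; the second was 0.03 at its highest among the alternatives, so its direction was not fixed. CYP11A1, which cleaves the cholesterol side chain in the first step of steroid synthesis, was lower in proximal cells of both follicles, 1.52-fold in F5 (1.48 to 1.56) and 1.963-fold in F1 (1.930 to 1.997).

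**Figure D1:**
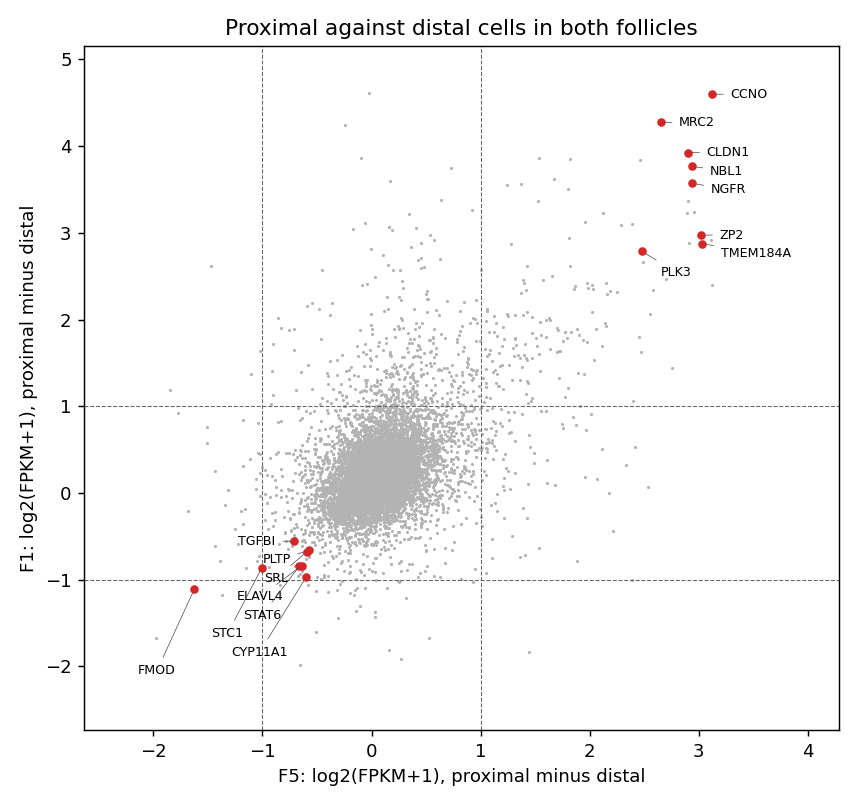
Each point is 1 of 11203 genes, with the proximal minus distal difference in log2(FPKM+1) in F5 follicles on the x axis and in F1 follicles on the y axis, from 1 library per group; dashed lines mark 2-fold. Red points are the 8 highest and 8 lowest in both follicles among genes with a usable symbol and a mean of at least 5 FPKM, and 153 genes lie beyond 2-fold in the upper right against 3 in the lower left.

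Between the follicles, 153 genes were at least 2-fold higher in proximal cells in both, where independent lists of these sizes would share 12.6, and 3 were at least 2-fold lower in both, where 0.109 would be shared. Another 6 genes differed 2-fold in opposite ways. Across genes, which are not independent replicates, the proximal-distal differences in F5 and F1 had a Pearson r of 0.47 and a Spearman rho of 0.36, and 66.3% had the same sign. Among genes with a usable symbol and a mean of at least 5 FPKM, CCNO, ZP2, NGFR, NBL1, CLDN1, TMEM184A, MRC2 and PLK3 were the highest in both. FMOD, STC1, STAT6, ELAVL4, CYP11A1, SRL, PLTP and TGFBI were the lowest in both among the same genes; PLTP, which transfers phospholipids between lipoproteins, was 1.49-fold lower in F5 (1.44 to 1.54) and 1.58-fold lower in F1 (1.56 to 1.61). In the additive limma fit with follicle as a block, 0 genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.0832. Unadjusted p-values lay below 0.05 for 1535 genes, and limma with voom weights on the recovered reads also called 0. With a pseudocount of 5 the fit called 154 higher and 5 lower genes, and after rescaling to a common total 31 and 0. Adjusted over the list alone, 4 of the 8 oocyte markers, 3 of 18 granulosa cell genes and 3 of 22 TGF-beta and BMP signalling genes were higher in proximal cells, against 0 of each over all genes tested. Of the 14 steroidogenesis genes, adjusted over the list alone, 2 were higher and 2 lower. The same count over the list alone gave 1 higher gene each for the ovulation, hypoxia and glycolysis, theca and stroma, endothelial and leukocyte lists, 1 lower leukocyte gene, and 0 for the others.

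The second question was how granulosa cells differ between F5 and F1. In the additive limma fit with position as a block, 1168 genes rose and 4010 fell from F5 to F1 at an adjusted p of 0.05. Proximal and distal cells served as the replicates of each follicle stage. The p-values of this fit may therefore leave out differences between hens or between follicles of the same stage. Under median-ratio scaling 2169 rose and 1896 fell, so the balance of the directions depends on the scaling, while a large set of genes differed under each. Luteinizing hormone receptor LHCGR (ENSGALG00000009095, chromosome 3, 7505304 to 7524818) rose by 4.09 on the log2 scale (SE 0.142, limma adjusted p = 0.00544). It stood at 32.9 and 29.3 FPKM in F5 proximal and distal cells and at 493.5 and 600.0 FPKM in F1. The receptor of follicle-stimulating hormone, FSHR, fell by 1.04 (SE 0.198, limma adjusted p = 0.0242), and was 1.64-fold lower in proximal (1.55 to 1.74) and 2.70-fold lower in distal cells (2.49 to 2.93). EPAS1 (ENSGALG00000010005, chromosome 3, 25951104 to 25982708), a hypoxia-inducible transcription factor, rose by 5.68 (SE 0.125, limma adjusted p = 0.00544), from 0.486 and 0.311 FPKM to 73.0 and 68.1 FPKM. PCP4, a calmodulin-binding peptide, had 2 and 0 reads in F5 proximal and distal cells and 406 and 327 in F1, which is 187.6-fold higher in proximal (51.6 to 1554) and at least 135.6-fold higher in distal cells. HTRA1, a secreted protease, was 32.1-fold higher in proximal (26.4 to 39.3) and 69.5-fold higher in distal cells (51.6 to 95.9). FAM84A, RPH3A, TMEM200C, PIP5K1B and CCK were also higher in F1 at both positions.

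CEL (ENSGALG00000003471, chromosome 17, 6773214 to 6778591), a lipase, fell by 5.23 (SE 0.198, limma adjusted p = 0.00544), from 106.8 and 122.7 FPKM to 2.61 and 1.63 FPKM. CTHRC1, a secreted collagen-related protein, was 20.5-fold lower in F1 proximal (17.8 to 23.7) and 82.4-fold lower in F1 distal cells (64.6 to 107). INHBB was 13.28-fold lower in proximal cells (11.99 to 14.74) and 811.3-fold lower in distal cells (373 to 2212), WNT4 6.75-fold (6.57 to 6.94) and 186.2-fold lower (160.5 to 217.2). FABP4, a fatty acid carrier, had 742 reads in F5 distal and 0 in F1 distal cells, at least 198.8-fold lower. TMEM72, EMP1 and COL14A1 also fell. RRP7A, RRP15, RRP36 and RRP12, which take part in the processing of ribosomal RNA, were between 18.5-fold (RRP12, 15.1 to 22.9) and 43.0-fold lower (RRP15, 20.6 to 108) in F1 proximal cells. They stand in a run of adjacent rows of the authors' table, and 51 other genes of this process had a median log2 difference of -0.43.

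**Figure D2:**
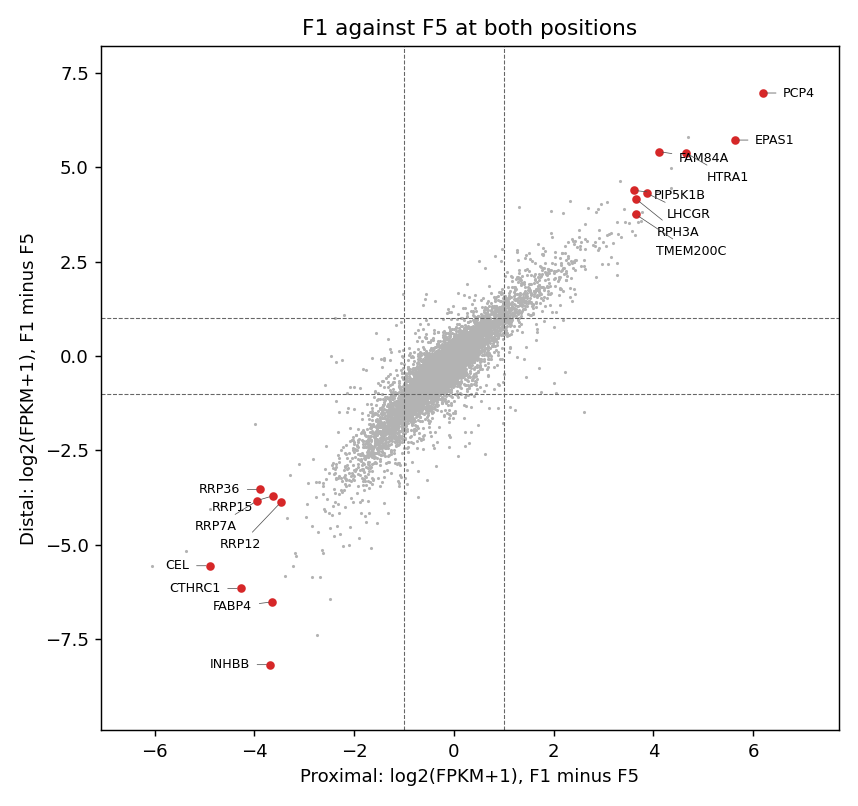
Each point is 1 of 11203 genes, with the F1 minus F5 difference in log2(FPKM+1) in proximal cells on the x axis and in distal cells on the y axis, from 1 library per group; dashed lines mark 2-fold. Red points are the 8 highest and 8 lowest at both positions among genes with a usable symbol and a mean of at least 5 FPKM, and the points lie along a diagonal with a Pearson r of 0.90 across genes.

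By the size rule 500 genes were at least 2-fold higher and 1103 at least 2-fold lower in F1 proximal than F5 proximal cells, and 601 higher and 1990 lower in F1 distal than F5 distal cells. Under median-ratio scaling the counts were 733 and 656, and 1071 and 1196. At both positions 433 genes were higher, where independent lists would share 26.8, and 1020 were lower, where 195.9 would be shared. Another 6 went opposite ways. The F1 against F5 differences in proximal and distal cells had a Pearson r of 0.90 and a Spearman rho of 0.87 across genes.

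Cell cycle genes fell together. Of 45 measured, 44 fell in the fit and 0 rose, with the same counts adjusted over the list alone. Their median log2 difference was -1.57 in proximal and -2.69 in distal cells, both at percentile 0.00. CDK1 stood at 64.5 and 50.8 FPKM in F5 and at 21.5 and 1.42 FPKM in F1 proximal and distal cells, and TOP2A at 62.9, 70.1, 12.9 and 5.04 FPKM in the same order. CCNB2 was not called (limma adjusted p = 0.149). Genes of cholesterol synthesis and uptake rose, 17 of 19 over all genes tested and 18 of 19 adjusted over the list alone, with medians of 1.20 and 1.43 at percentile 100. HMGCS1, an early enzyme of the pathway, rose by 3.10 (SE 0.1004, limma adjusted p = 0.00544) and was 9.34-fold higher in proximal (8.87 to 9.84) and 8.09-fold higher in distal cells (7.74 to 8.45). Of 14 steroidogenesis genes 5 rose and 5 fell, with the same counts adjusted over the list alone. STAR, which carries cholesterol into mitochondria, rose by 2.68 (SE 0.137, limma adjusted p = 0.00796), CYP11A1 by 1.46 (SE 0.128, limma adjusted p = 0.0109) and HSD3B2 by 1.66 (SE 0.096, limma adjusted p = 0.00907). CYP17A1, HSD17B1 and NR0B1 fell. The list's medians of -0.05 and -0.24 lay at percentiles 85.6 and 62.5.

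**Figure D3:**
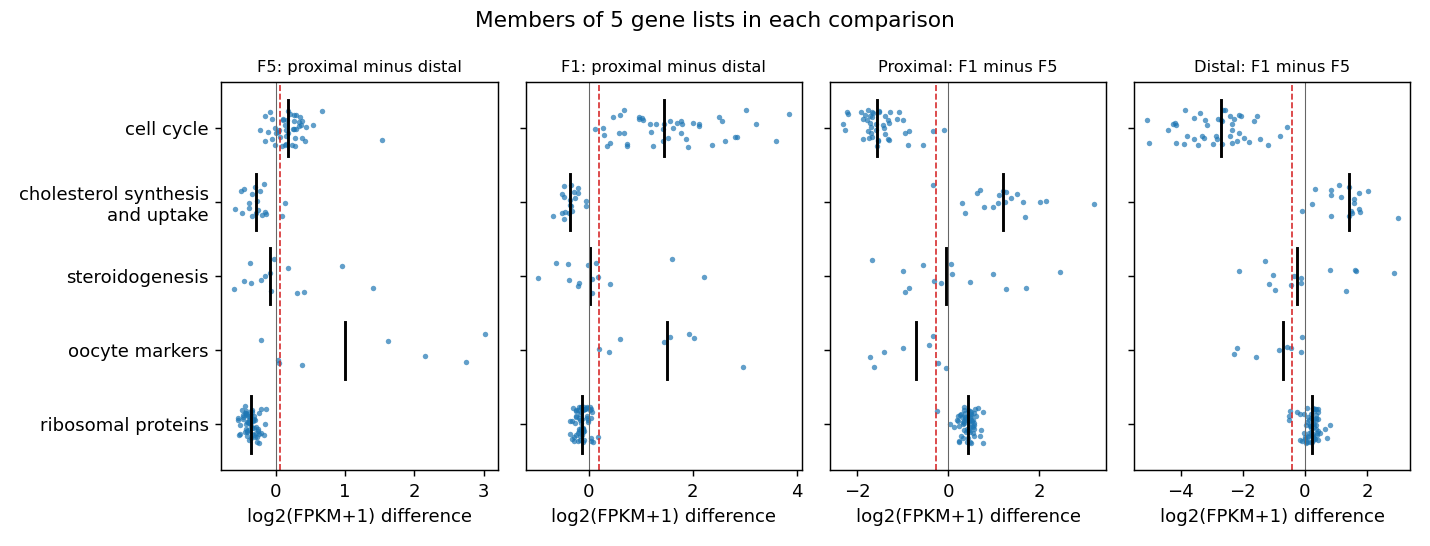
Blue points are the measured genes of 5 lists, placed by their log2(FPKM+1) difference in the 4 comparisons (x axes, own scale in each panel, vertical jitter only for display); black bars are list medians and red dashed lines the median of all 11203 genes. Cell cycle genes have medians of 0.17, 1.46, -1.57 and -2.69 from left to right.

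Of 18 granulosa cell genes 4 rose and 5 fell, over all genes and adjusted over the list alone. INHBA, the beta A subunit, was 12.08-fold higher in F1 proximal cells (11.01 to 13.28) and 12.04-fold higher in distal cells (11.04 to 13.15), the opposite direction to INHBB. ZP3 rose by 2.72 (SE 0.185, limma adjusted p = 0.01004) and FOXL2, a transcription factor of granulosa cells, by 0.64 (SE 0.098, limma adjusted p = 0.0172), from 1054.8 and 860.9 FPKM to 1593.9 and 1390.7 FPKM. AMH fell by 1.12 (SE 0.231, limma adjusted p = 0.0278). Among receptors 4 of 12 rose and 3 fell, with 4 and 4 adjusted over the list alone. TGF-beta and BMP signalling had 3 of 22 that rose and 7 that fell, and WNT signalling 3 of 23 and 11, or 3 and 12 adjusted over the list alone; SMAD3 and WNT16 were among those that rose. The WNT list had a median of -0.74 in distal cells at percentile 1.27, which moved to percentile 19.3 without the filter and to 2.82 at a mean of at least 5 FPKM. Of the proteases and their inhibitors 4 of 12 rose and 5 fell; TIMP2, an inhibitor of metalloproteinases, was 13.2-fold higher in proximal cells (11.4 to 15.2), and ADAMTS9 stood at 57.8 and 61.5 FPKM in F5 and at 8.42 and 0.782 FPKM in F1. Basement membrane and matrix genes had 6 of 18 up and 7 down. The ovulation list had 1 of 10 up and 4 down, and the hypoxia, glycolysis and angiogenic list 7 of 26 up and 13 down, with the same counts adjusted over each list alone. Apoptosis genes had 1 of 16 up and 7 down and innate immune genes 1 of 8 up and 3 down, again with the same counts over the list alone. Immediate early and stress genes had 3 of 14 up and 5 down, or 4 and 6 over the list alone, with JUN up by 2.73 (SE 0.105, limma adjusted p = 0.00544). The TGF-beta and BMP medians, -0.16 in proximal and -0.24 in distal cells, reached 0.15 and 0.21 among the alternatives. The hypoxia medians, -0.23 and -0.28, reached 0.07 and 0.10. Medians of the granulosa, receptor, protease, matrix, immediate early and innate immune lists also took both signs, so the direction of these lists was not fixed.

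Ribosomal protein genes had medians of 0.44 in proximal and 0.23 in distal cells, at percentiles 100 and 99.98, and 24 of 62 rose while 0 fell; adjusted over the list alone 2 rose. Oxidative phosphorylation genes had 4 of 48 up and 8 down, or 2 and 5 over the list alone, and mitochondrially encoded genes 0 of 12 up and 5 down by either count. The medians of the first list, -0.05 in proximal and -0.12 in distal cells, reached 0.25 and 0.35 among the alternatives. Those of the second, -0.26 and -0.29, reached 0.06 and 0.18, so the direction of neither list was fixed. Markers of other cell types were few. Theca and stroma markers had 6 measured members, of which 2 fell, or 3 adjusted over the list alone, and the highest was COL1A2 at 11.7, 6.93, 11.8 and 6.55 FPKM in F5 proximal, F5 distal, F1 proximal and F1 distal cells. Endothelial markers had 1 of 5 up and 1 down. Erythrocyte and thrombocyte markers had 2 measured members, with HEMGN at 754.9, 839.0, 391.3 and 331.1 FPKM and TUBB1 at 1.87, 1.67, 1.30 and 1.33 FPKM; 1 of them, HEMGN, fell. The globin gene HBAA, at 0.649, 0.415, 0.4 and 0 FPKM, was below the expression minimum. Of 2 measured leukocyte markers 0 were called, and IRF8 stood at 13.4, 6.47, 11.1 and 6.30 FPKM. Of 8 oocyte markers 3 fell from F5 to F1 and 0 rose, and BUB1B, also counted in the cell cycle list, is among those that fell.

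**Figure D4:**
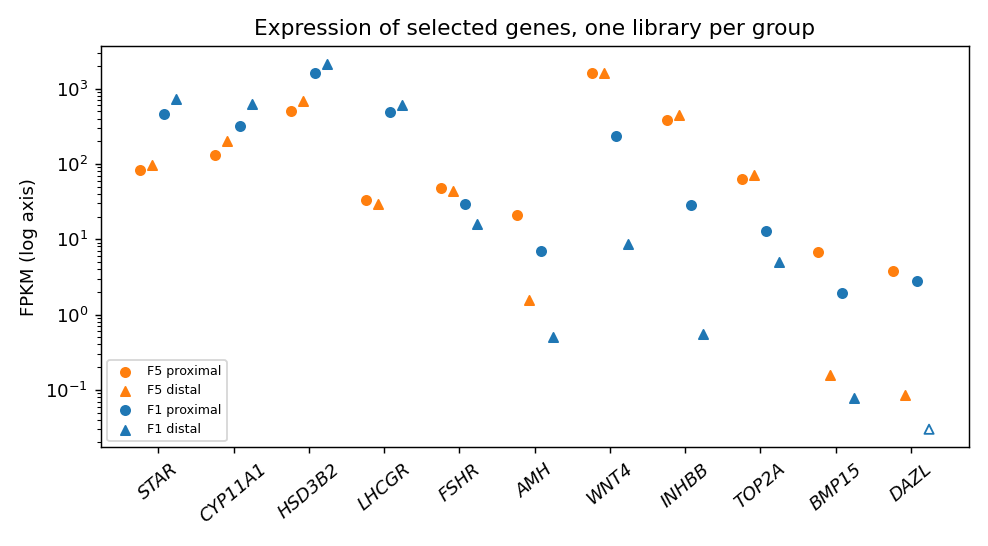
FPKM on a log axis of 11 genes in the 4 libraries; circles are proximal and triangles distal cells, orange F5 and blue F1, and an open symbol marks a value of 0 drawn at the bottom. LHCGR lies at 32.9 and 29.3 FPKM in F5 and at 493.5 and 600.0 FPKM in F1, and AMH is higher in proximal cells of both follicles.

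The authors' deposited table gives log2 fold changes of proximal against distal cells for 14812 genes in F5 and 14013 in F1. They equal the log2 ratio of FPKM less a constant of 0.0928 in F5 and 0.237 in F1. Of the 11203 genes, 11180 in F5 and 11114 in F1 have such a value. Among these, the authors' deposited table has 361 genes at least 2-fold higher and 124 at least 2-fold lower in F5 proximal cells, and 811 and 158 in F1.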

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

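The results were recomputed under the alternatives named above; thinning and the voom fit were chosen after the data were seen. A count was taken to have moved when it changed by more than 1.5 times, and a list when it entered or left the middle 95% of random lists. Of the counts of genes 34 of 84 alternatives moved, of the counts from the fits 6 of 36, and of the list medians 8 came outside that range, 9 came inside and 527 did neither; the correlations moved in 0 of 28. For the named genes, 6407 alternatives stayed on the same side of 2-fold in the same direction, 127 dropped under 2-fold, 100 passed it and 170, all under 2-fold in the analysis reported, changed sign. The cause of a move was not tested unless given.

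With a pseudocount of 0.1, which widens differences of low genes by construction, 404 genes were higher and 76 lower in F5 proximal than distal cells, 1076 and 77 in F1, and 233 and 6 in both. With a pseudocount of 5, which narrows them, the counts were 68 and 1 in F5, 148 and 4 in F1, and 45 and 1 in both. For F1 against F5 it gave 283 higher and 463 lower genes in proximal cells, 333 and 918 in distal cells, and 249 and 442 in both. The position fit with this pseudocount called 154 higher and 5 lower genes.

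Without the filter on low values 62 genes were lower in F5 proximal cells. At a mean of at least 5 FPKM, which leaves fewer genes, 105 were higher and 8 lower in F5, 331 and 13 in F1, and 59 and 1 in both; 727 were lower in F1 than F5 proximal and 1320 in F1 than F5 distal cells.

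Under median-ratio scaling, which by construction moves the median of all genes towards 0, 91 genes were lower in F1 proximal than distal cells and 7 in proximal cells of both follicles. For F1 against F5 it gave 656 lower genes in proximal cells, 1071 higher and 1196 lower in distal cells, and 666 higher and 598 lower in both, and the follicle fit called 2169 and 1896. After rescaling to a common total the position fit called 31 higher genes. With the other factor left out the follicle fit called 2618 lower genes.

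Of 80 list medians 21 lay outside the middle 95% of random lists, and 15 of these did so under every alternative run. Lists that came inside were, in F5 position, WNT signalling (0.0539 without the filter, -0.0466 at a mean of 5 FPKM) and endothelial markers (0.20 with a pseudocount of 5, 0.0457 without the filter). In F1 position they were TGF-beta and BMP signalling (0.19 without the filter), and at a mean of 5 FPKM immediate early genes (0.33) and oxidative phosphorylation (-0.0138). In F1 against F5 distal cells it was WNT signalling (-0.28 without the filter, -0.70 at a mean of 5 FPKM). Lists that came outside were steroidogenesis in F5 position (-0.10 with a pseudocount of 0.1 and -0.10 after thinning), matrix genes in F5 position (-0.0331 without the filter) and in F1 against F5 proximal cells (0.0575 with a pseudocount of 5, 0.37 by median ratio), proteases in F1 position (0.42 at a mean of 5 FPKM), and oocyte markers in F1 against F5 (-0.46 in proximal cells with a pseudocount of 5, -1.87 in distal cells with 0.1).

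The replicate numbers link no libraries as pairs, since each group has 1 library; proximal and distal cells were compared within follicle by the position fit with follicle as a block. Leaving out a library leaves no residual degrees of freedom for an additive fit, so it was not run. The planned edgeR test on recovered reads was not run.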

Other observations

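All tests below were chosen after the data were seen, thinning of the reads before its own result was seen and the others after theirs. The count of genes at least 2-fold higher in proximal cells of both follicles was 153 as reported and 153 after thinning all libraries to the shallowest, which argues against the lower depth of the F1 distal library. A candidate explanation is oocyte RNA carried into the proximal libraries, since the germinal disc lies beside these cells and the labels name no sort that would remove it. Of 19 listed oocyte markers with at least 20 reads, 17 had more FPKM in proximal cells of both follicles (not RNF17 and SYCP3). Among the 17, PLK4 (224 and 226 reads) and TDRD1 (115 and 113 reads) were near equal in F5 proximal and distal cells. By the authors' log2 fold changes, which subtract 0.0928 in F5, both would lie below 0, so the count depends on the scaling. The medians of all genes also lay above 0 in both follicles (0.07 and 0.20), and the share of all genes higher in both was not computed. Of the 19 markers, 5 reached 1 FPKM in F5 distal cells, 1 listed gene is also a cell cycle gene, and the highest, ZP2, reached 28.8 FPKM. Over 52 of the 153 genes, those with at least 20 reads in both distal libraries, the slope of the log2 ratio of added FPKM on that of distal levels was 0.35 (95% bootstrap interval 0.15 to 0.54), which holds neither the 0 of an equal addition nor the 1 of an equal fold; because these genes were chosen by their fold, which ties the added amount to the distal level, the slope does not decide on an equal addition. How many of the 153 genes have this origin is open, and so is a different state of granulosa cells near the disc, which the design names and which was not tested. AMH, made by granulosa cells, was among the 153, at 21.2 against 1.55 FPKM in F5 and 6.96 against 0.508 FPKM in F1. By 2-fold or more, 3 of 18 granulosa cell genes in F5 and 6 in F1 were higher in proximal cells, and 0 lower. The medians of that list lay at percentiles 92.0 and 88.65. Whether the oocyte holds RNA of these genes was not measured. EMCN, an endothelial marker, was among the 153 genes, at 10.6 against 0.986 FPKM in F5 and 3.67 against 0.116 FPKM in F1. Of 17 endothelial markers found by name 5 reached the mean of 1 FPKM, and of 17 theca and stroma markers 6 did. Among those that did, 5 and 4 of 5 endothelial markers lay above 0 in F5 and F1, and 5 and 5 of 6 theca and stroma markers. The medians of these 2 lists lay at percentiles 98.3 and 74.45 in F5 and at 44.5 and 32.8 in F1. Whether RNA of other cell types adds to the 153 genes was not tested.

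Cell cycle genes were higher in proximal cells of F1 by a median log2 of 1.46, and by 0.17 in F5. Thinning left the F1 median at 1.42, which argues against depth. Oocyte RNA may add to the F1 difference: the FPKM added in F1, put on top of the F5 distal library, predicts a median of 0.29 in F5, which is 0.12 above the observed value. More FPKM was added in F1 than in F5 for 40 of 45 cell cycle genes (medians 5.68 and 2.72). For oocyte markers outside that list the same held for 8 of 18 (medians 0.446 in F1 and 0.362 in F5). Among these 18, the largest additions in F5 were to ZP2, BMP15, DAZL and KPNA7. Less was added in F1 than in F5 to ZP2 (8.39 against 26.1 FPKM), BMP15 (1.85 against 6.62) and DAZL (2.8 against 3.72). More was added in F1 to KPNA7 (3.07 against 2.84). The higher F1 median of the markers was therefore not shared by ZP2, BMP15 and DAZL. F5 distal cells also hold RNA of cell cycle genes, such as BUB1B at 12.1 FPKM. The amount added in F5 can therefore mix differences among granulosa cells with carried RNA. For this reason the comparison does not decide on a source of like makeup in both follicles. The makeup of oocyte RNA was not measured, so oocyte RNA stays open as an explanation. A later stop of division in cells near the disc stays open and was not tested.

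A run of adjacent rows in the alphabetical table, RRNAD1, RRP12, RRP15, RRP1B, RRP36 and RRP7A, had a median F1 minus F5 log2 difference of -3.67, the lowest of any window of 6 genes; RRNAD1 and RRP1B were singled out after their values were seen. Of 1000 random orders of the genes 0 gave a window as low, the lowest being -2.68. A general fall of rRNA processing genes of this size is not borne out, since 51 others had a median of -0.43 (quartiles -0.58 and -0.27). F1 FPKM values written on neighbouring rows could produce such a run, but 6 of 6 genes gave whole reads in the 4 libraries at 1 gene length within the 99th percentile of all genes, where 1.30% of 1000 rows shifted on purpose did. A shift in the authors' read counts before FPKM were computed was not tested and stays open, and so does a biological difference between the follicles; the run's values should be checked against the reads.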
